A study of Homo sapiens with 6 samples.

How the data were processed

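PolyA-selected RNA from BE-(2)-C neuroblastoma cells was sequenced 48 hours after control siRNA or ELF4 siRNA treatment, with 3 libraries in each of 2 groups. RNA was isolated with Trizol per the labels' protocols. The deposited table holds a signal that is a normalised read count per gene. Per the submitters' processing notes, TopHat, featureCounts, DESeq2 and the hg19 build were used. Their versions, their roles, the gene annotation, the strand setting and any filter are not given in the sources used here. Every value divided by what 1 read is worth in its library was whole within 0.001 (100% of values), so whole reads were recovered for all 6 libraries, and the deposited values are read counts divided by a size factor per library. The size factors were 1.06, 0.875 and 1.41 for control replicates 1 to 3, and 0.908, 0.891 and 0.966 for ELF4 siRNA replicates 1 to 3. The recovered depth was 23148635 to 38097986 reads per library.

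The table has 26906 rows, and the smallest row total is 11 reads over the 6 libraries. In 2148 rows several gene names are joined, and these hold 11.4% of the reads. For 2037 names a row of their own exists beside the joined row, so levels of overlapping or near-identical genes are uncertain. The values of 516 rows equal those of another row, 8 of them with a mean of at least 100. Genes and antisense partners cannot be told apart, since no strand setting is stated. Names were used as the table gives them. The reference used here, GENCODE 29, is on another build than hg19, so no genomic coordinates are given, and positions within transcripts refer to GENCODE 29.

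The comparison was ELF4 siRNA against control siRNA without covariates. Because the values were normalised by the authors, the main test was limma on log2(value + 1) with a trend in the moderation, and not a count model. Fold changes are on that scale, which understates changes of genes with few reads. Genes with a value of at least 10 in at least 3 libraries were tested, and the Benjamini-Hochberg adjusted p threshold was 0.05. Nothing in the labels beyond treatment in triplicate says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Libraries of the same group differed by more than sampling noise, as the chi-square per degree of freedom of the reads was 2.27 to 6.73, so all 6 libraries were used. The biological coefficient of variation in edgeR was 4.2%.

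Before the data were examined, 25 gene lists were written from textbook knowledge. They hold 768 genes counting repeats, of which 692 were matched by symbol, 11 by an older symbol, and 65 had no row of their own. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists. Also fixed were the rule for named genes and the alternatives. The rule named ELF4. It then named the 7 largest rises and the 7 largest falls among called genes with a mean of at least 100 in the higher group and no overlap between the groups. From each list it took the up to 2 members with the smallest adjusted p. Some genes that the rule names are not reported here.

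The alternatives were other pseudocounts, filters and scalings, limma without the trend, edgeR and DESeq2 on the recovered reads, a replicate block, leaving out each library, camera with an estimated correlation, and fry. A correction for transcript length and GC content was added after seeing the data. It is void for counts of genes, because only 72.7% of tested genes had a length and GC value. The search of 3′ UTRs for 7-mers and the NF-kB, actin, histone and 7SK tests were also added after seeing the data. In the search, fold changes limited to 1 on the log2 scale in either direction were adjusted for 3′ UTR length and GC content. For each of 15713 7-mers found in at least 100 of 9922 genes, z was the mean difference between genes with and without it over its standard error.

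The tests were tested on simulated data for ELF4 siRNA against control siRNA. Over 20371 genes, limma recovered 69% of genes changed by 0.5 on the log2 scale and 82.7% of those changed by 1, and called 9 unchanged genes (5.7% of calls). Camera gave an adjusted p of 1.58e-34 for a shifted list and 0.404 for an unchanged one. The simulated genes were independent of one another and the lists random, so camera was not tested on lists of correlated genes. Only 100 tested genes were changed by 0.5 and 98 by 1, where the data called 45.1% of genes. In the 7-mer search over 9922 genes, a planted 7-mer ranked 1 with a z of -9.65, and the lowest z with nothing planted was -3.68. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.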

Results

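RNA abundance was measured in BE-(2)-C cells, a human neuroblastoma cell line with an amplified MYCN gene, 48 hours after treatment with an siRNA against ELF4 or with a control siRNA. ELF4 encodes a transcription factor of the ETS family, and the series title ties it to the microRNA miR-124, to growth and to the undifferentiated state. The question was therefore which genes of the cell cycle, of neuronal differentiation and of the progenitor state differed between the groups. Each group had 3 libraries of polyA-selected RNA. The reads recovered from the deposited values numbered 28586317, 23148635 and 38097986 in control replicates 1, 2 and 3, and 24251545, 23770924 and 25408746 in ELF4 siRNA replicates 1, 2 and 3. Mitochondrial rows held 5.81% to 6.44% of the reads. Values are given as the mean normalised read count ± SD, with n = 3 libraries per group throughout, and changes as the log2 fold change of ELF4 siRNA over control siRNA.

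ELF4 itself fell to 11.1% of its control level. Its normalised read count was 42.4, 38.8 and 46.8 in control replicates 1, 2 and 3, and 5.5, 5.6 and 3.1 in ELF4 siRNA replicates 1, 2 and 3. These values rest on 45, 34 and 66 reads in the control libraries and on 5, 5 and 3 reads in the ELF4 siRNA libraries, so the remaining level is known only roughly. The mean went from 42.7 ± 3.96 to 4.74 ± 1.42, a log2 fold change of -2.96 (SE 0.25, limma adjusted p = 5.38e-07). An exact permutation test of the 6 values, two-sided, gave p = 0.1, the smallest that 3 libraries against 3 allow.

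After ELF4 siRNA, 46 of 46 tested G2/M genes and 43 of 46 tested G1/S genes fell, and 36 of 48 tested genes of neuronal differentiation rose. With an estimated correlation these lists did not pass (adjusted p = 0.0659, 0.336 and 0.336). Of 20339 genes tested, 4217 rose and 4956 fell, together 45.1% of those tested. Most of these changes were small, since 6137 of the 9173 called genes (66.9%) had an absolute log2 fold change under 0.5, while 333 genes rose and 241 fell by at least 1 on the log2 scale. The values of the groups did not overlap in 53.6% of tested genes, where chance gives 10%. The axis of largest variance separated the groups and held 63.9% of the variance. Correlations of log2 values between libraries were 0.9949 to 0.9963 within groups and 0.9849 to 0.9872 between them.

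**Figure D1:**
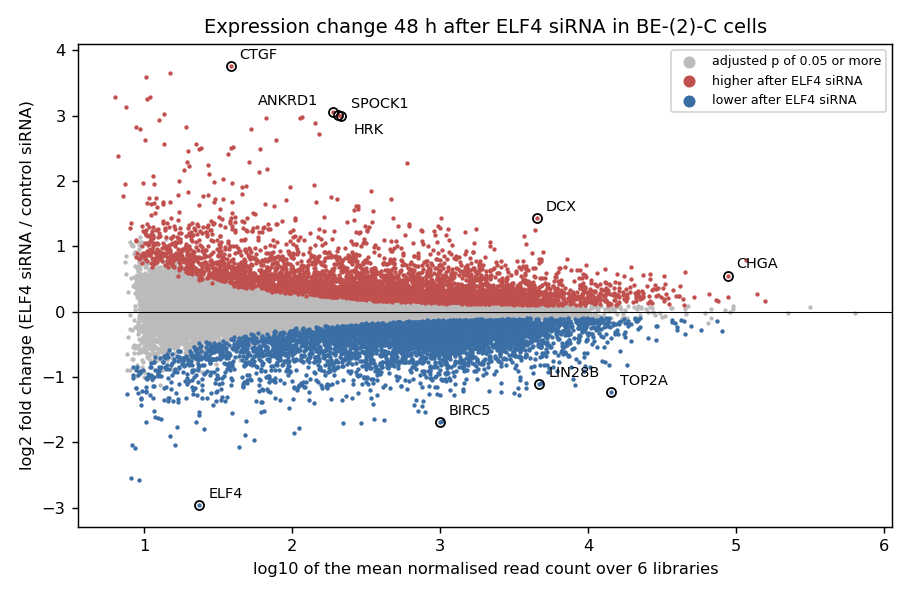
Log2 fold change of ELF4 siRNA over control siRNA (vertical axis) against log10 of the mean normalised read count over the 6 libraries (horizontal axis), with 1 point per tested gene. Red points are the 4217 genes that rose, blue points the 4956 that fell and grey points those that did not pass, and ELF4 lies at -2.96.

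The largest rises and falls were ranked among called genes with a mean of at least 100 in the higher group and no overlap between groups. Within these limits the 7 largest rises were in ANKRD1, SPOCK1, HRK, RELB, NEBL, LINC00890 and RN7SKP71. CTGF, with a mean of 72.7 after ELF4 siRNA, rose more (3.76) but lies below that mean. ANKRD1, a cardiac ankyrin repeat protein, went from 39.1 ± 3.01 to 342 ± 106 (log2 fold change 3.06, adjusted p = 7.82e-09), and SPOCK1, a secreted proteoglycan, from 44.6 ± 8.71 to 364 ± 36.5 (3.01, adjusted p = 1.66e-09). HRK, a BH3-only protein that promotes apoptosis, went from 47.5 ± 7.30 to 383 ± 40.5 (2.99, adjusted p = 9.62e-10), and RELB, an NF-kB subunit, from 26.3 ± 10.3 to 207 ± 33.1 (2.98, adjusted p = 9.25e-08). NEBL, which encodes an actin-binding protein, rose with a log2 fold change of 2.96 and the noncoding gene LINC00890 with 2.96. RN7SKP71, a copy of the 7SK small nuclear RNA, rose with a log2 fold change of 2.89 (adjusted p = 1.25e-05). It shares sequence with near-identical copies, so its own level is uncertain. Its control values were 19.8, 22.8 and 72.3, and control replicate 3 held 3.15 times the mean of the other controls in the signal summed over 7SK and its copies.

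The largest falls within the same limits included BIRC5, which encodes the mitotic regulator and apoptosis inhibitor survivin. BIRC5 went from 1521 ± 31.8 to 472 ± 13.4 (log2 fold change -1.69, adjusted p = 1.17e-10). RBPMS2, an RNA-binding protein gene, had a log2 fold change of -1.85 and HOMER1, which encodes a synaptic scaffold, of -1.77. CRB2, a gene of epithelial polarity, and TMEM119, a transmembrane protein gene, each had -1.70. SEPT3, a neuronal septin, had -1.67 and EPAS1, the gene of the hypoxia factor HIF-2alpha, -1.65. The adjusted p of these 7 genes ranged from 1.17e-10 for BIRC5 and SEPT3 to 4.99e-06 for HOMER1. RBPMS2, BIRC5, SEPT3 and EPAS1 carry the 7-mer ACCTGTC or the overlapping CCTGTCA in the 3′ UTR of their GENCODE 29 transcript. One of these 7-mers was present in 55 of the 95 genes with a log2 fold change of -1 or lower (57.9%) and in 2054 of the other 9827 genes (20.9%). This search covered genes with a mean of at least 100 and an annotated 3′ UTR, and was made after the fold changes were known. Both 7-mers were picked by their association with lower fold changes in these same genes, so these shares describe that choice and are no test of it.

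Genes of the cell division cycle fell as a group. All 46 tested G2/M and mitosis genes fell, with a median log2 fold change of -0.53 (camera adjusted p = 1.45e-25 with the preset correlation, adjusted p = 0.0659 with an estimated correlation). TOP2A, the topoisomerase that untangles chromosomes, went from 20130 ± 915 to 8589 ± 301 (-1.23, adjusted p = 3.07e-10), and BIRC5 belongs to the same list. Of the 46 tested genes of G1/S and DNA replication, 43 fell, 0 rose and 3 did not pass, with a median of -0.40 (adjusted p = 2.21e-18, and adjusted p = 0.336 with an estimated correlation). RFC5, a subunit of the clamp loader, went from 1849 ± 25.7 to 1019 ± 64.0 (-0.86), and PCNA, the sliding clamp, from 8201 ± 58.9 to 5637 ± 115 (-0.54). TOP2A has a 3′ UTR match to ACCTGTC, whereas RFC5 and PCNA have none. CCNB1 (-0.76) and MKI67 (-0.20), chosen after their values were seen, also fell.

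Genes of neuronal differentiation moved the other way. Of 48 tested, 36 rose, 6 fell and 6 did not pass, with a median log2 fold change of 0.27 (camera adjusted p = 1.65e-08, and adjusted p = 0.336 with an estimated correlation). DCX, which encodes the microtubule protein doublecortin of young neurons, went from 2448 ± 37.7 to 6590 ± 56.0 (1.43, adjusted p = 5.89e-11) although its 3′ UTR carries both 7-mers. In the adrenergic lineage list, 14 of 28 genes rose, 7 fell and 7 did not pass, and the list did not pass (adjusted p = 0.0976). CHGA, the chromogranin of secretory granules, went from 71160 ± 2528 to 104400 ± 5687 (0.55), and HAND2, a transcription factor of sympathetic neurons, from 13710 ± 509 to 18570 ± 558 (0.44).

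Stem and progenitor markers were lower in part. Of 24 tested, 13 fell, 2 rose and 9 did not pass, with a median log2 fold change of -0.16, and the list did not pass (camera adjusted p = 0.0908). LIN28B, an RNA-binding protein that blocks let-7 maturation, fell from 6402 ± 611 to 2967 ± 278 (-1.11, adjusted p = 3.44e-08) and has a 3′ UTR match to CCTGTCA. NES, the intermediate filament nestin of neural progenitors, fell from 3747 ± 153 to 2541 ± 118 (-0.56, adjusted p = 4.70e-07). MYCN, chosen after its value was seen, went from 78440 ± 2727 to 70990 ± 4027 (-0.14, adjusted p = 0.0189).

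**Figure D2:**
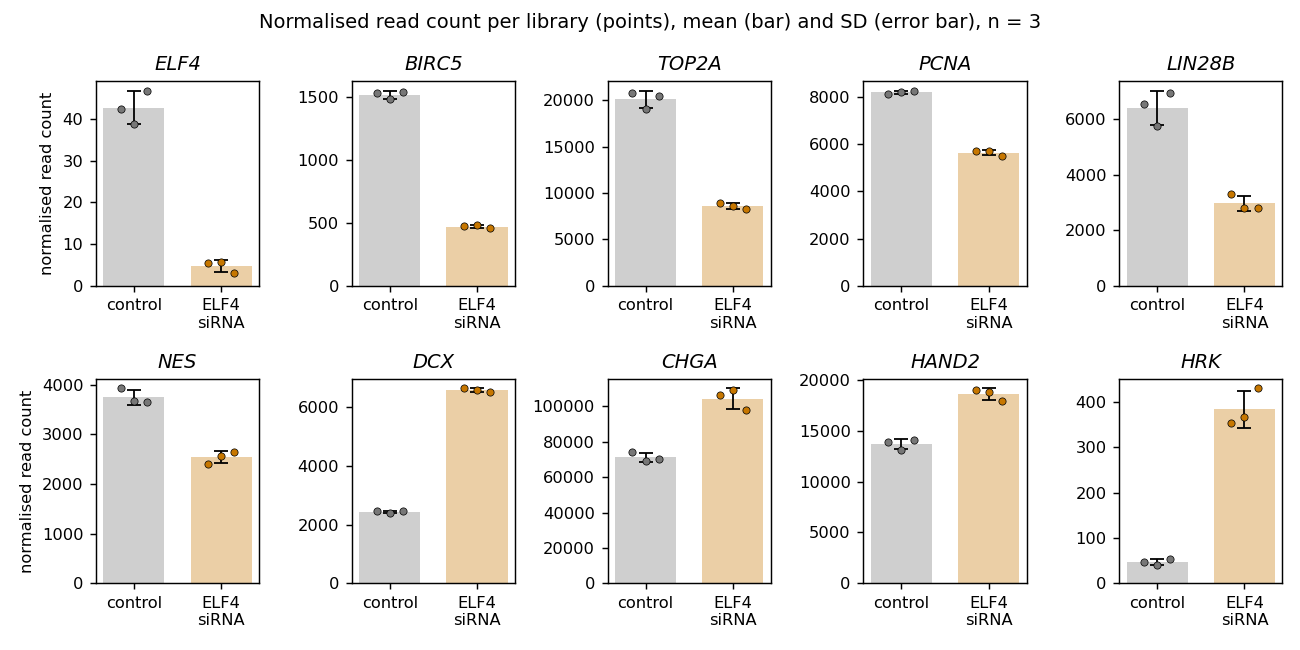
Normalised read count (vertical axis, from 0) of 10 genes in each of the 6 libraries (points), with the mean (bar) and SD (error bar) of the 3 libraries per group. ELF4, BIRC5, TOP2A, PCNA, LIN28B and NES were lower and DCX, CHGA, HAND2 and HRK higher in all 3 ELF4 siRNA libraries than in any control library.

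Cytosolic ribosomal protein genes rose by a small amount. Of 36 tested, 31 rose, 1 fell and 4 did not pass, with a median log2 fold change of 0.24 (camera adjusted p = 2.52e-10, and adjusted p = 0.388 with an estimated correlation). RPL3 went from 26370 ± 1473 to 38630 ± 1316 (0.55) and RPS18 from 27930 ± 1069 to 35890 ± 545 (0.36). These genes have processed pseudogenes of nearly the same sequence, so the reads of single members are uncertain. Of the 32 tested MYC targets and ribosome biogenesis genes, 13 fell, 3 rose and 16 did not pass (adjusted p = 0.13), among them the nucleolar helicase gene DDX21 (-0.75, with a match to ACCTGTC) and WDR43 (-0.39).

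The lists of hypoxia and glycolysis and of extracellular matrix and TGF-beta response held members that moved in both directions, and each list passed near the threshold. Of 30 tested genes of hypoxia and glycolysis, 17 fell, 5 rose and 8 did not pass, with a median of -0.18 (camera adjusted p = 0.0435, and adjusted p = 0.363 with an estimated correlation). PGAM1, a glycolytic mutase gene with pseudogenes, fell from 9882 ± 301 to 5526 ± 289 (-0.84), and KDM3A, a histone demethylase gene, rose from 769 ± 12.4 to 1269 ± 94.9 (0.72). Of 33 tested genes of extracellular matrix and TGF-beta response, 15 rose, 7 fell and 11 did not pass, with a median of 0.24 (adjusted p = 0.0435, and adjusted p = 0.712 with an estimated correlation). The laminin genes LAMA4 (1396 ± 17.2 to 2930 ± 115, 1.07) and LAMB1 (6942 ± 84.4 to 10790 ± 64.2, 0.64) rose. In the overlapping fibroblast list, 6 of 10 tested markers rose and 3 fell (adjusted p = 0.13), with PDGFRB at -1.19 and a match to CCTGTCA, and DCN at 0.83. COL1A1 (0.48) and COL3A1 (1.75) rose and count in both the matrix and the fibroblast list. The hypoxia call was lost without ELF4 siRNA replicate 1 (adjusted p = 0.0535), and the matrix call without control replicate 2 (0.11) or ELF4 siRNA replicate 3 (0.12). It was also lost with a replicate block (0.0545), and both were lost when only genes with a mean of at least 100 were tested (0.111 and 0.218).

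**Figure D3:**
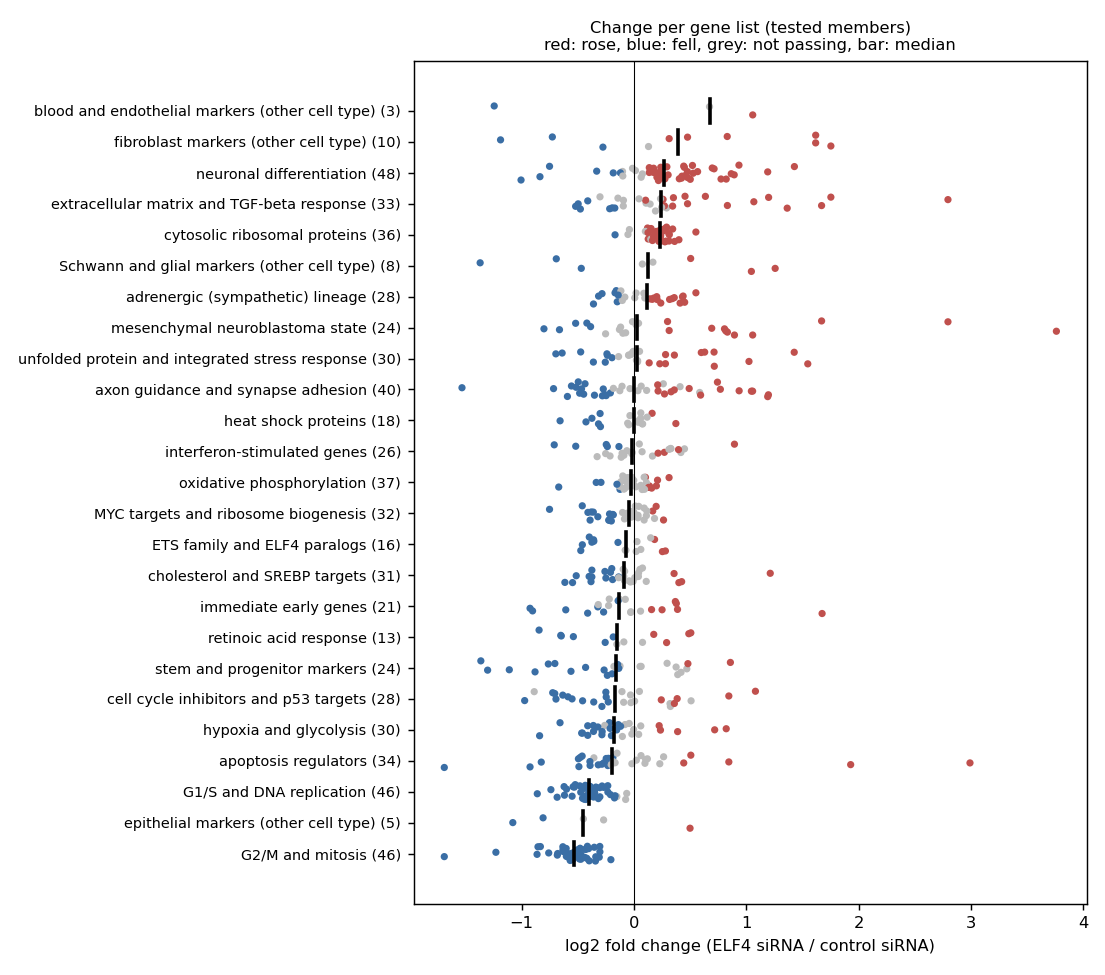
Log2 fold change of ELF4 siRNA over control siRNA (horizontal axis) for each tested member of the 25 gene lists (vertical axis, number of tested members in brackets), with the median as a black bar. Red points rose, blue points fell and grey points did not pass, and the G2/M list, with all 46 members below 0, has the lowest median at -0.53.

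The lists of stress and death held members that moved in both directions, and none passed camera. Among 34 apoptosis regulators, 16 fell, 5 rose and 13 did not pass (camera adjusted p = 0.13), with HRK as the largest rise and BIRC5 as the largest fall. Of 28 cell cycle inhibitors and p53 targets, 13 fell, 5 rose and 10 did not pass (adjusted p = 0.195). TP53INP1 rose (1.08), ZMAT3 fell (-0.70), and CDKN1A, the p21 inhibitor gene chosen after its value was seen, fell (-0.97). In the list of unfolded protein and integrated stress response, 12 of 30 rose, 8 fell and 10 did not pass (adjusted p = 0.231). CHAC1 rose from 179 ± 2.19 to 527 ± 59.7 (1.55) and VLDLR, which carries both 7-mers, from 553 ± 6.22 to 1490 ± 109 (1.43). Of 18 heat shock genes, 6 fell, 2 rose and 10 did not pass (adjusted p = 0.279), with BAG3 at -0.66 and CACYBP, which has a match to ACCTGTC, at -0.37. Their median was 0 and their mean -0.08. Of 21 immediate early genes, 7 fell, 6 rose and 8 did not pass (adjusted p = 0.54), with MCL1 at -0.92 and EGR1 at -0.90.

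The remaining lists did not pass camera either. Mesenchymal state genes numbered 11 that rose, 5 that fell and 8 that did not pass (adjusted p = 0.14), with the matrix genes CTGF (4.35 ± 1.43 to 72.7 ± 26.8, 3.76) and FN1 (1102 ± 28.5 to 2309 ± 342, 1.06). Cholesterol and SREBP targets numbered 13 that fell, 4 that rose and 14 that did not pass (0.13), with TM7SF2 at 1.21. Interferon-stimulated genes numbered 4 that rose, 5 that fell and 17 that did not pass (0.735), with IRF1, which carries both 7-mers, at 0.90. Their median was -0.02, while their mean of 0.03 and the test pointed up. For the 37 oxidative phosphorylation genes, 7 rose, 5 fell and 25 did not pass (0.812), with NDUFA8 at -0.67 and NDUFB10 at -0.34. For the 40 genes of axon guidance and synapse adhesion, 14 rose, 16 fell and 10 did not pass (0.735), with NRP1 at 0.77 and LRRTM2 at 0.94. The 13 retinoic acid genes had 4 that rose, 6 that fell and 3 that did not pass (0.368), with NRIP1 at -0.65 and BCL2, which has a match to CCTGTCA, at 0.51. Of 16 ETS family genes, 3 rose, 7 fell and 6 did not pass (0.279), with ELK3 at -0.47 and ELK1 at -0.46.

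The Schwann, epithelial and blood markers held members that rose and members that fell. Of 8 Schwann and glial markers, 3 rose and 3 fell (camera adjusted p = 0.279), with PMP22 at 1.26. Of 5 epithelial markers, 1 rose and 2 fell (adjusted p = 0.368), with CLDN4 at -1.08 and KRT19 at 0.50. Only 3 blood and endothelial markers were tested, too few for a set test, with CD14 at -1.24 and PTPRC at 1.06. Counts adjusted over the list alone equalled those over all genes except in 10 lists. The rises and falls were then 33 and 1 for ribosomal proteins, 5 and 18 for hypoxia, 17 and 9 for matrix, 14 and 8 for adrenergic, 5 and 13 for MYC targets, and 4 and 14 for cholesterol. They were 5 and 14 for p53 targets, 4 and 7 for retinoic acid, 6 and 5 for oxidative phosphorylation, and 2 and 1 for blood markers.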

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

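The length and GC correction was chosen after seeing the data, and the other alternatives before. All 1047 values of the named genes under the alternatives kept their direction and side of the threshold. For the lists, 418 values kept their side of the threshold, but direction was not compared where neither value passed. Of the other list values, 19 passed the threshold where the main value had not and 17 no longer passed. Where the main or the alternative value passed, 0 reversed direction. The numbers of genes that rose and fell stayed within 1.5 times of 4217 and 4956, except that 333 and 241 passed with an absolute log2 fold change of at least 1, by construction of that limit. Over the alternatives, edgeR called 4454 and 4807 genes, DESeq2 3442 and 4079, and leaving out 1 library gave totals of 7658 to 9070. Apart from that limit and the length and GC correction, between 80.8% and 100% of the main calls were shared with each alternative, all in the same direction. With an estimated correlation the list calls were lost for G2/M (adjusted p = 0.0659), G1/S (0.336), neuronal differentiation (0.336) and ribosomal proteins (0.388), which passed under all other alternatives (adjusted p of at most 3.29e-05, 0.000399, 0.000399 and 0.00212), and the cause was not tested. The stem and progenitor list, at 0.0908, passed without a filter (0.0412), with a mean of at least 100 (0.0372), with DESeq2 (0.0376) and with fry (0.000571), which does not compare a list with other genes, and its range was 0.000571 to 0.363. The adrenergic list passed with DESeq2 (0.0148) and without control replicate 1 (0.0499), with a range of 0.0148 to 0.712. The fibroblast list, at 0.13, passed upward with DESeq2 (0.0413) and fry (0.023), with a range of 0.023 to 0.712. Fry called 19 lists where camera called 6, so a fry call is not particular to the stem and fibroblast lists. Among them were apoptosis regulators (fry adjusted p = 0.000875), p53 targets (0.0162), immediate early genes (0.0168) and heat shock genes (0.023). The hypoxia call was also lost without the trend (0.0602), with edgeR (0.0659), with DESeq2 (0.0507) and with the length and GC correction (0.0668), and the matrix call without the trend (0.0606); the ranges were 0.00178 to 0.363 and 0.00699 to 0.712. Whether the replicate numbers pair the libraries is not settled. The correlations of same-numbered deviations were small, at 0.029, 0.075 and 0.041, against -0.057 to 0.015 for other pairs between the groups. All 6 libraries correlated best with their own number, a hint of pairing from the data and not the design. With the replicate block 4564 genes rose and 5346 fell, 9910 in all, and of the list calls only the matrix one was lost (0.0545). Depth limits the precision of the ELF4 level, which rests on 3 to 5 reads per ELF4 siRNA library.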

Other observations

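All tests in this part were chosen after the fold changes were seen. The comparison of the lowest with the highest 7-mer z was set before any z of a 3′ UTR 7-mer was seen, for all genes with a 3′ UTR and with an adjustment for length, while the adjustment for GC content, the minimum mean and the limit on fold changes were not set then. Genes of NF-kB signalling were higher after ELF4 siRNA in part. Of 20 pathway and target genes, 10 rose and 3 fell, and their median log2 fold change of 0.20 lay at the 99.22 percentile of 10000 random lists matched on expression. RELB (2.98), NFKB2 (1.29), NFKBIE (0.45) and the targets BIRC3 (1.93), TNFAIP3 (1.79) and CCL2 (2.93) rose, and TRAF1 was at -0.21 (limma adjusted p = 0.29). BIRC3, TNFAIP3 and CCL2 had low control means of 21.1, 6.91 and 2.27, so the size of their rises is known only roughly. Of 16 actin and YAP/SRF target genes, 7 rose and 3 fell, with a median of 0.24 at the 99.28 percentile. CTGF (3.76), ANKRD1 (3.06), ACTA2 (1.62) and TAGLN (1.62) rose, CNN1 fell (-0.80), and TPM1 was at -0.07. ACTA2 and TAGLN also belong to the fibroblast list. The members of both lists were picked after their values had been seen, so the percentiles describe them and are no independent evidence.

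HMOX1, a heme-degrading enzyme gene, rose from 89.3 ± 11.6 to 315 ± 141 (log2 fold change 1.73). Of 47 histone genes, 30 rose, 0 fell and 17 did not pass in limma, with a median of 0.72. HIST1H2AC (1.37), HIST1H2BD (1.10), HIST2H2BE (1.05), HIST1H1C (0.76) and HIST1H2BK (0.59) rose, while HIST1H1B was at -1.12 (adjusted p = 0.077). Near-identical histone genes can share reads, so single members are uncertain.

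The 7-mer ACCTGTC in 3′ UTRs had the lowest z, -13.54, against 4.78 for the highest. Its 1154 genes had a mean log2 fold change of -0.188, against -0.041 for the rest. Next came GCCTGTC (-12.04), CCTGTCA (-11.8) and CCTGTCT (-10.06), which share a 6-mer with it. CCTGTCA, which overlaps ACCTGTC and has the same bases, was taken as its partner. Sites of GCCTGTC and CCTGTCT were not counted as matches of genes. ACCTGTC was picked for the lowest z of all, so no other 7-mer could fall below it. The 406 other 7-mers of the same bases without the shared 6-mer CCTGTC reached no lower than -3.81. Only the size of this gap argues against base composition. The reverse complement was at 1.09. ELF4 carries the 8-mer ACCTGTCA, at positions 870 to 877 of its 4145-base transcript ELF4-202, in the coding sequence, as do 7.0% of 2618 transcripts of similar length, so a candidate explanation is repression of other genes by seed matches of the ELF4 siRNA, whose sequence is not given in the sources used here. The 17 G2/M and 17 G1/S genes without the shared 6-mer anywhere in the transcript used still had lower values after ELF4 siRNA. Their medians were -0.49 (95% interval -0.567 to -0.398) and -0.381 (-0.429 to -0.269), with intervals over genes and not over libraries. Direct matches to this 6-mer in those transcripts therefore do not account for these falls. Other sites were not excluded, since a 7-mer without the 6-mer, CTGTCTT, had a z of -6.49. Indirect effects of matched genes and of the loss of ELF4 cannot be told apart with these libraries.

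The 7SK small nuclear RNA RN7SK rose from 125.3, 125.7 and 461.2 in the controls to 850.4, 779.0 and 1249.2 after ELF4 siRNA. Reads moving between its copies would leave their sum level, but the sum had a log2 ratio of 2.124 against a control SD of 0.957. Whether carry-over of RNA without a poly(A) tail is the cause stays open. A first test, the median of 6 such rows with a mean of at least 100 (-0.646, interval -0.831 to -0.076), argued against it, but 5 of the 6 rows are 7SL RNA, so it was replaced, after its result was seen, by sums over 6 RNA families with a summed mean of at least 50. The highest ratio among these 6 was then 0.585, for U1 RNA, and without control replicate 3 U1 was at 2.109 against 2.904 for 7SK, while RPPH1 (0.715), RMRP (0.614), scaRNAs (0.29), snoRNAs (-0.011) and 7SL RNA (-0.378) were lower. A family below that minimum, 1 row of other U RNA with a mean of 15.9, had a ratio of 1.176, and 2.113 without control replicate 3. In control replicate 3, U1 (2.728), RMRP (2.316), RPPH1 (2.123) and the other U RNA (1.904) were also above the other controls (log2). There 7SL RNA was at 0.631, scaRNAs at 0.168 and snoRNAs at 0.066. Since scaRNAs and snoRNAs hardly followed 7SK in that library, their flat ratios say little. U1, at a mean of 51.1 near that minimum, and the other U RNA go with carry-over, and 7SL RNA goes against it. RMRP and RPPH1 were at -0.604 and -0.369 with control replicate 3 but rose without it, so they do not decide. Carry-over cannot be told apart from a change in 7SK.

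The histone rise may also be carry-over, because many replication-dependent histone RNAs lack a tail, although which rows hold such RNA was not tested. The median of the 47 histone genes in control replicate 3, the control library with more 7SK, was 0.362 (log2) above the other controls, which goes with it. The rows of HIST1H2AC, HIST1H2BD, HIST2H2BE, HIST1H1C and HIST1H2BK go against carry-over, if their RNA lacks a tail. They rose after ELF4 siRNA but were within -0.032 to 0.134 (log2) of the other controls in that library. HIST1H1B, HIST1H1D, HIST1H1E and HIST1H3B were 1.04 to 1.87 higher there and at -1.12 to -0.41, not passing, after ELF4 siRNA. Their changes were taken over all controls, and the high values in that library lower them. HIST1H1D, for example, was 8.5, 11.4 and 21.3 in the controls and 8.8, 11.2 and 8.3 after ELF4 siRNA. The negative sign of these changes therefore says nothing about carry-over. Across the 47 genes, which are not independent replicates, a Spearman rho between the rise in control replicate 3 and that after ELF4 siRNA was -0.147, but both were taken over the same controls, which moves rho upward with no effect, so it was replaced after its result was seen. With a separate control under each, rho was -0.185 (permutation p = 0.216) and, with these controls swapped, -0.368 (permutation p = 0.0097), with a mean of -0.277. Since this rests on 1 library and on rows chosen after their values were seen, carry-over stays open, and no biological explanation was tested.

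The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. Only 1 of the 10, the real split, called as many genes in limma (9173), and the highest other called 0. In the real split 10523 genes, and in the others up to 515, had an unadjusted p under 0.05. Every other split mixes both treatments within each group, so the contrast between treatments adds to its spread and lowers its calls. The 0 is therefore no measure of the calls that chance would give. For lists, 4 of the 10 splits called at least the 6 of the real one, and the highest other called 7. The G2/M list passed camera in all 10, with an adjusted p of 1.45e-25 in the real split and 2.19e-07 to 6.32e-06 in the others. The other splits still hold part of the contrast between the groups, so these values do not show how small such a p gets without it. With fry, the real split called 19 lists and the others 0, where 21 lists of the real split and up to 1 of the others had an unadjusted p under 0.05. The same mixing of treatments lowers the fry calls of the other splits, so they are no measure of chance either.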
